A study of Mus musculus and Drosophila melanogaster and Arabidopsis thaliana with 49 samples.

How the data were processed

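Reads were trimmed with Trimmomatic 0.36, aligned with Bowtie 1.2.1.1 to TAIR10 (Arabidopsis), BDGP6 (Drosophila) or GRCm38 (mouse) and handled with DESeq2, per the submitters' processing notes. The 4 deposited tables hold log2 values per mature miRNA and library from the authors, with lowest values of -2.57, -2.16, -2.16 and -2.96 in Arabidopsis, fly, liver and plasma. The transformation is not given in the sources used here, and neither are the mismatch settings, the version of the miRNA annotation or the treatment of reads that match several hairpins. The values have the shape of a shrunken log2 transform such as a regularized logarithm, in which low entries are drawn towards their mean over libraries. Log2 changes, summed antilogs and shares are therefore on that scale and not on that of reads, most of all for low entries. Read depth per library is unknown. The summed antilogs, which depend on that transformation, ranged from 101313 to 1106404 per library in Arabidopsis, 579290 to 720880 in fly, 1435061 to 3542524 in liver and 555692 to 6024074 in plasma.

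The tables have 394 names in 9 Arabidopsis libraries, 243 IDs in 14 fly libraries, 970 names in 12 liver libraries and 1168 names in 14 plasma libraries, and all libraries were kept. Liver columns were read by their codes: Tri as TRIzol, HQE as TraPR, D as digested with RNase T1 and ND as not digested. If D and ND were swapped, the sign of the RNase T1 contrasts and of the interaction would turn, and the contrasts of TraPR with TRIzol before and after digestion would change places. The numbers in the fly TraPR titles were used as given. miRNAs with a mean log2 value of at least 3 in 1 group of their table were tested: 229 in Arabidopsis, 134 in fly, 327 in liver and 277 in plasma, and 122 for the trend along the fly TraPR numbers.

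Before the data were examined the groups, the 17 contrasts, the lists, the rule for naming miRNAs and the first set of alternatives were fixed, and the test planned was a quasi-likelihood test on counts. Because the values are log2 and not counts, limma 3.58.1 replaced it after the data were seen: linear models per table over all libraries with empirical Bayes variances that follow the mean (trend = TRUE), moderated t-tests, and Benjamini-Hochberg adjustment over the miRNAs tested in a contrast, called at adjusted p under 0.05. The main fit had no block for replicate number. Scaling to the same summed antilog took the place of other size factors for counts. Centring each column on its median, a minimum of log2 5, averaging copies of a mature name, a variance without trend, a block for the liver column-name suffix and a block for the plasma replicate number within the kit were chosen after seeing the data, as was leaving out each library for the arm and list tests.

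Lists were tested with limma's camera at a preset correlation of 0.01 between members, two-sided and adjusted over the lists of a contrast, with an estimated correlation as alternative, and a list needed at least 3 tested members. The Arabidopsis lists were conserved land-plant families, floral and organ development, copper, phosphate and sulfate response, regulators of the silencing machinery, triggers of trans-acting siRNAs, DCL4-dependent miRNAs, entries with high numbers (400 and above) and less abundant arms. The mouse lists were hepatocyte, erythroid, leukocyte and platelet, stromal and smooth muscle, let-7, miR-17-92 and paralogs, the Dlk1-Dio3 cluster, entries with high numbers (1900 and above) and less abundant arms, and in plasma also striated muscle and the Sfmbt2 cluster. Membership was written from general knowledge and not taken from a database. Fly lists were not tested because the table carries IDs without miRNA names.

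Hairpins with both arms tested entered an exact two-sided sign test of the change of the less abundant arm minus that of the other. The less abundant arm was the one with the lower share of the summed antilogs, added over all libraries of the table. Numbers of miRNAs at log2 3 or more and the share of the most abundant miRNA were compared by exact two-sided permutation tests, adjusted over 14 comparisons for each measure. Groups were called separated when all values of one lay above all values of the other, which happens by chance for 10% of miRNAs with 3 against 3 libraries, 2.86% with 4 against 4, 33.3% with 2 against 2 and 5.71% with 3 against 4. Overlaps of calls were compared with a one-sided hypergeometric test only between contrasts without shared libraries.

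Within the Lexogen kit, deviations from the group means correlated at 0.299 to 0.609 between TRIzol and TraPR libraries of the same replicate number, and averaged -0.154 between other numbers. The labels do not state such pairing, so it was read from the data and the block was added beside the unblocked fit.

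Named miRNAs were those past adjusted p 0.05 with separated groups and the largest changes (up to 8 each way in the first contrast of TraPR with its reference in a table, up to 3 each way elsewhere), the 10 with the highest mean, and up to 4 members of each list with the highest mean. The 8 miRNAs named as lower with both plasma kits and those shared with liver were named after the values were seen where that rule does not reach them. Hairpin coordinates are 1-based GRCm38 positions from GENCODE vM21, the build that the submitters' notes name. Sharing of 20-base words was sought in GENCODE vM21 transcripts, which hold few nuclear tRNA and ribosomal RNA genes. Genes that overlap a hairpin were left out of that search.

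The fit was tried on simulated values with the groups and spread of each table and 20 miRNAs changed at each size. All sizes were changed in the same run, which eases the adjusted threshold, so recovery may be lower where few miRNAs change. In Arabidopsis it recovered 40% of changes of 1 on the log2 scale, 85% of 2 and 100% of 4 for TraPR against total RNA, 50%, 85% and 100% against gel-selected RNA and 60%, 95% and 100% for gel-selected against total RNA. In fly it recovered 85% or more at each size. In liver it recovered 35%, 90% and 100% for TraPR against TRIzol, 30%, 80% and 100% for RNase T1 in TRIzol, 40%, 90% and 100% for RNase T1 in TraPR, 50%, 90% and 100% after RNase T1 and 20%, 45% and 95% for the interaction. In plasma it recovered 45%, 85% and 100% with the Lexogen kit, 15%, 70% and 100% with the TruSeq kit, 20%, 65% and 100% and 20%, 90% and 100% for the kits within TRIzol and TraPR, and 15%, 60% and 90% for the interaction. False calls numbered 0 to 6 per contrast.

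Tools were Python 3.11.15, R 4.3.3, limma 3.58.1, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.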

Results

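The data were small RNA sequencing libraries that set TraPR, a column purification of small RNAs while they sit in RNA-induced silencing complexes, against libraries made after other isolations. From Arabidopsis inflorescences there were 3 libraries each of TRIzol total RNA, of TRIzol RNA size-selected on a gel and of TraPR. From Drosophila ovaries there were 2 libraries each of ribodepleted RNA, of ribodepleted and oxidized RNA, and of TraPR at each of the numbers 50, 25, 10, 5 and 2, whose unit the labels do not state. From mouse liver there were 3 libraries each of TRIzol and TraPR, with and without digestion by RNase T1, an enzyme that cuts unprotected RNA after guanosine. From mouse plasma there were 4 TRIzol and 4 TraPR libraries made with a Lexogen kit and 3 of each made with a TruSeq kit. Values are log2 abundances per mature miRNA as the authors deposited them, so the read depth of the 49 libraries is unknown, and they have the shape of a shrunken scale. Which liver libraries were digested was read from column codes, and all liver directions with RNase T1 rest on that reading. Changes are differences of group means ± the standard error (SE) of a limma fit, with p-values adjusted over the miRNAs tested in that table, and group values are means ± SD. The labels do not say whether replicates are separate animals, plants or cages, so these p-values may measure technical spread only. Where a name below stands for several near-identical copies (the miR160, miR165, miR166, miR-486, miR-199, miR-692 and let-7 families, and names with a copy number after a point), the split of reads between copies is uncertain.

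Replicate libraries correlated closely across miRNAs, which are not independent replicates of one another. The lowest Pearson correlation within a group was 0.968 in Arabidopsis, 0.998 in fly ovary, 0.987 in liver and 0.957 in plasma. The number of miRNAs at a log2 value of 3 or more was 176 ± 2.08 in Arabidopsis TraPR, 197 ± 8.02 after gel selection and 182 ± 7 in total RNA (n = 3 each). It was 302 ± 7.51 in liver TraPR and 309 ± 1 in liver TRIzol (n = 3 each). In plasma it was 243 ± 8.21 for TraPR and 253 ± 5.48 for TRIzol with the Lexogen kit (n = 4 each), and 217 ± 15.0 and 239 ± 7.55 with the TruSeq kit (n = 3 each). Across 14 comparisons of these numbers the lowest adjusted p was 0.233 in exact two-sided permutation tests, which cannot go below a raw p of 0.1 with 3 libraries against 3 or 0.0286 with 4 against 4.

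Whether TraPR gives the same Arabidopsis miRNAs as TRIzol total RNA was asked first. Among the named miRNAs, miR160b and miR160a-5p of the miR160 family, which targets auxin response factors, rose most. miR160b rose by 8.79 ± 0.34 (SE, n = 3 per group, adjusted p = 8.32e-25 by limma), from 1.0 ± 0.49 in total RNA to 9.79 ± 0.32 in TraPR, and miR160a-5p by 6.28 ± 0.30. miR160b was also higher in gel-selected than in total TRIzol RNA, so its low value in total RNA was not shared by both TRIzol groups. miR472-3p, a regulator of disease resistance genes, rose by 5.41 ± 0.34, the phosphate-responsive miR2111b-5p by 5.26 ± 0.49, miR822-3p by 5.19 ± 0.44 and miR164a, which limits organ boundary genes, by 4.82 ± 0.43. miR172b-3p, a repressor of APETALA2-like genes, rose by 4.77 ± 0.32 and miR773a by 4.66 ± 0.33. The log2 change was -6.12 ± 0.52 for miR861-3p (adjusted p = 1.12e-13), -5.97 ± 0.31 for the passenger arm miR166b-5p, -5.89 ± 0.32 for miR166a-5p, -5.70 ± 0.53 for miR5646, -4.95 ± 0.40 for miR8175, -4.80 ± 0.34 for miR8166, -4.25 ± 0.39 for miR5653 and -3.96 ± 0.50 for miR166e-5p. Each of these 16 changes separated all 3 TraPR from all 3 total RNA libraries, which the rule for naming them required.

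**Figure D1:**
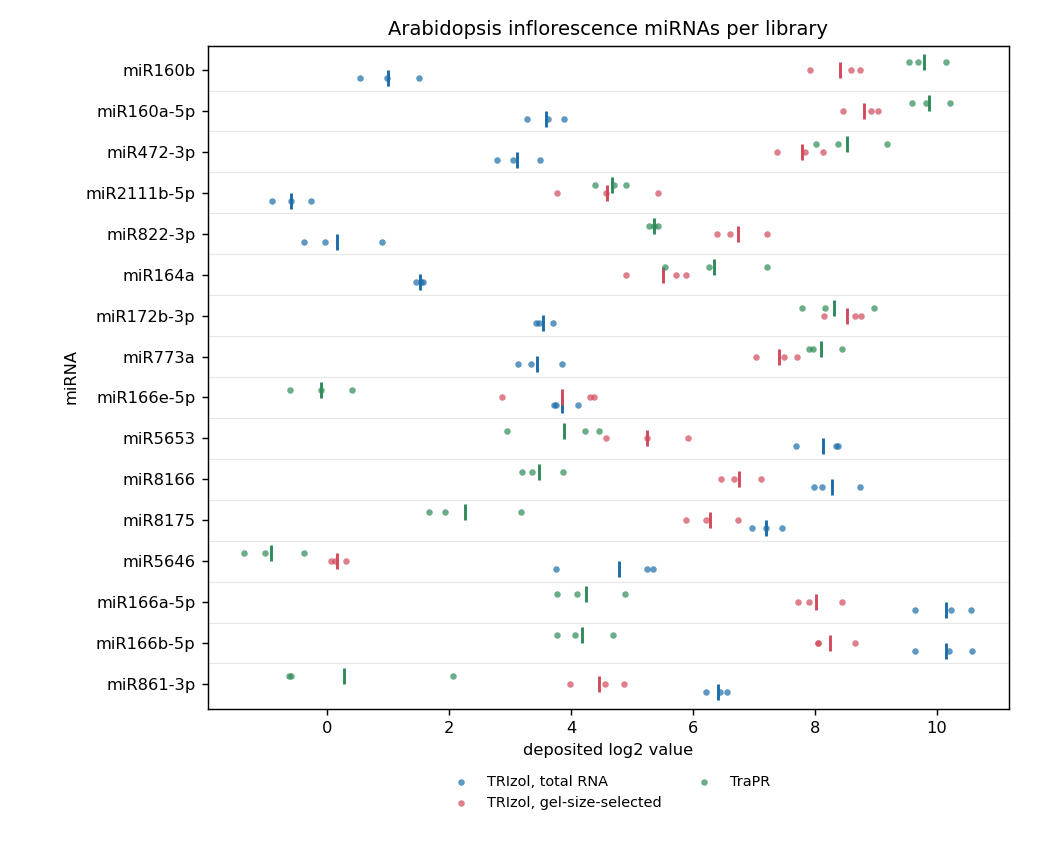
Log2 abundance in each Arabidopsis library (dots) and group mean (ticks) for the 16 miRNAs with the largest changes between TraPR and TRIzol total RNA, 8 in each direction, with the gel-selected group beside them. miR160b lay at 1.0 ± 0.49 in total RNA and at 9.79 ± 0.32 in TraPR, and miR861-3p at 6.40 ± 0.18 and 0.28 ± 1.55.

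The most abundant Arabidopsis miRNAs moved less. miR166a-3p, a guide strand that targets class III HD-ZIP genes, fell by 1.79 on the log2 scale (SE 0.30, adjusted p = 1.67e-06 by limma), from 17.2 ± 0.24 to 15.4 ± 0.45. Its call held in all 13 alternatives. The copies miR166b-3p, miR166c, miR166d, miR166f and miR166g passed too (adjusted p from 0.000194 to 0.000255 by limma). Each of those calls ended in at least 1 of 13 alternatives, with a highest adjusted p of 0.119 to 0.143 by limma. miR158a-3p (-0.60 ± 0.33, adjusted p = 0.0985 by limma) and miR159a (0.63 ± 0.33, adjusted p = 0.0813) did not pass, and the sign of miR158a-3p turned to 0.37 when columns were scaled to the same summed antilog. In all, 163 of 229 tested miRNAs passed, 69 up and 94 down, and 174 separated the groups, against 10% expected by chance. Summed antilog scaling moved the median of all miRNAs by 0.96 and the split to 99 up and 54 down, whereas centring on the median gave 69 up and 92 down.

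No miRNA list fixed before the data were examined passed limma's camera test in TraPR against total RNA (adjusted p 0.696 to 0.988). Of the conserved land-plant families 31 members rose and 43 fell among 100 tested, and of the floral and organ development families 20 rose and 27 fell among 58. The copper, phosphate and sulfate response list had 3 up and 2 down of 11, and the regulators of the silencing machinery (miR162, miR168 and miR403) had 1 up and 7 down of 10, with a median of -0.99. The triggers of trans-acting siRNAs had 2 up and 4 down of 6, the DCL4-dependent miRNAs 2 up and 1 down of 3, entries with high numbers 34 up and 48 down of 118, and the less abundant arms of hairpins 13 up and 23 down of 47. Counts adjusted over the list alone were the same for these 8 lists. The median, mean and test differed in sign for the conserved families (-0.40, 0.06, up), the floral families (-0.49, 0.11, down) and the nutrient list (-0.22, -0.02, up). Equal summed antilogs turned the medians of 5 lists from negative to positive (0.57 for the conserved families and 0.48 for the floral families), and left -0.03 for the silencing regulators and -0.36 for the siRNA triggers.

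The major miRNA family was lower in gel-selected than in total RNA of Arabidopsis. Against total RNA, miR166d changed by -5.53 ± 0.30 (adjusted p = 1.02e-19), miR166a-3p by -5.49 ± 0.30 and miR166b-3p by -5.45 ± 0.30 (n = 3 per group). The miR165 and miR166 guide strands held 70.9% ± 6.62 of the summed antilogs in total RNA, 13.5% ± 1.74 after gel selection and 56.4% ± 6.42 in TraPR. miR158a-3p changed by -3.17 ± 0.33, a call that ended with columns scaled to the same summed antilog (-0.17, adjusted p = 0.524 by limma), while miR167a-3p rose by 8.14 ± 0.32, miR160b by 7.41 ± 0.34 and miR172e-5p by 6.64 ± 0.47. Of 229 miRNAs, 167 passed, 77 up and 90 down, and 175 separated the groups, against 10% by chance. Here scaling moved the balance far: the same summed antilog shifted the median by 3.0 and gave 183 up and 11 down, with the family's median still at -2.38, and centring shifted it by -0.47 and gave 63 up and 110 down. None of the 8 lists passed camera (adjusted p 0.469 to 0.620).

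TraPR compared with gel-selected RNA had more miR165 and miR166. miR165b rose by 4.66 ± 0.29 (adjusted p = 6.75e-17, n = 3 per group), miR165a-3p by 4.48 ± 0.29 and miR166d by 4.26 ± 0.30, and each stayed above 2 under the other scalings (2.62, 2.44 and 2.22 at the lowest). miR172e-5p changed by -6.47 ± 0.47, miR172b-5p by -4.40 ± 0.45 and miR156d-3p by -4.20 ± 0.45. Of 229 miRNAs 136 passed, 67 up and 69 down, and 145 separated the groups, against 10% by chance. Scaling to the same summed antilog shifted the median by -2.04 and gave 13 up and 183 down, and centring shifted it by 0.43 and gave 94 up and 45 down.

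The balance of hairpin arms was compared because TraPR is meant to isolate guide strands in Argonaute. In TraPR against gel-selected RNA the less abundant arm moved below its partner in 36 of 47 hairpins, with a median difference of -1.20 (exact two-sided sign test, p = 0.000346, and p from 9.85e-05 to 0.00309 when any 1 of the 6 libraries was left out). As a list, these arms had 4 up and 26 down of 47, also adjusted over the list alone, with a median of -1.28 (-3.32 and -0.85 under the other scalings) and an adjusted p of 5.55e-05 by camera. With an estimated correlation the adjusted p was 0.0519, the only 1 of 9 alternatives (2.82e-05 to 0.0519) that missed the threshold. The sign test does not depend on how columns are scaled, but family members are not independent, and among the 14 hairpins whose less abundant arm had a mean antilog of at least 50 the exact test gave p = 0.424. The less abundant arm was chosen from all 9 Arabidopsis libraries, those compared among them. Where gel-selected RNA differs from both other groups, that choice favours a lower arm in TraPR. The sign and list tests are therefore not independent of it, and its part in the shift was not tested. Against total RNA the less abundant arm was lower in 27 of 47 hairpins (p = 0.382, exact sign test), and in gel-selected against total RNA in 17 of 47 (p = 0.0789, exact sign test).

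In fly ovaries TraPR at the number 50 came close to ribodepleted RNA. The largest rise was for FBgn0262407 (1.64 ± 0.34, adjusted p = 0.00801 by limma, n = 2 per group) and the largest fall for FBgn0262400 (-3.64 ± 0.33, adjusted p = 3.39e-06 by limma), and these IDs carry no miRNA names in the deposited table. The rise of FBgn0262407 no longer passed without ribodepleted replicate 2 (1.18, adjusted p = 0.0724 by limma, with 5.78e-26 to 0.0724 over its 12 alternatives). Of 134 tested miRNAs 17 passed, 10 up and 7 down, and 70 separated the groups, against 33.3% by chance. The count was 8 without ribodepleted replicate 1, 9 without ribodepleted replicate 2 and 5 without TraPR replicate 2. Summed antilog scaling shifted the median by -0.13 and gave 4 up and 17 down, and centring shifted it by 0.11 and gave 22 up and 4 down.

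Oxidation, which leaves end-methylated small RNAs able to ligate, changed the fly profile far more than TraPR did. FBgn0262200 rose by 3.15 ± 0.18 (adjusted p = 3.43e-10, n = 2 per group) and FBgn0262367 changed by -2.79 ± 0.14 (adjusted p = 1.38e-10) against ribodepleted RNA. The most abundant miRNA was FBgn0262420 in the ribodepleted libraries and FBgn0262223 in the oxidized libraries. The share of whichever was most abundant was 35.1% ± 0.195 of the summed antilogs after oxidation and 11.1% ± 0.524 before. This difference had the smallest exact two-sided permutation p that 2 against 2 allows (0.333). Of 134 miRNAs 105 passed, 49 up and 56 down, and 114 separated the groups, against 33.3% by chance. Centring on the median shifted the median by 0.38 and gave 59 up and 46 down.

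TraPR at the lowest and highest numbers could not be told apart in fly ovary. Between the numbers 2 and 50 limma called 0 of 134 miRNAs, with 1 at an unadjusted p under 0.05 and 34 separating the groups, against 33.3% by chance (n = 2 per group). Along the log2 of the numbers limma called 0 of 122 miRNAs over the 10 TraPR libraries, with 5 at an unadjusted p under 0.05. In simulated data of the same size, all 20 miRNAs changed by 1 on the log2 scale were recovered in both comparisons.

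Few liver miRNAs passed between TraPR and TRIzol. The hepatocyte miRNA miR-122-5p (0.78 ± 0.72, adjusted p = 0.920 by limma) and miR-192-5p, the most abundant (-0.10 ± 0.58, adjusted p = 0.990 by limma, and 0.02 and 0.03 under the other scalings), did not pass (n = 3 per group). The log2 change was -5.54 ± 0.84 for miR-5099 (adjusted p = 0.00139 by limma), -4.55 ± 0.72 for miR-3963, -3.47 ± 0.83 for miR-3535, -2.71 ± 0.36 for miR-5100 and -2.69 ± 0.43 for miR-2137, and miR-6236 (-2.23 ± 0.48) and miR-5121 (-1.89 ± 0.38) completed the 7 that fell. In GRCm38 the Mir5099 hairpin lies outside other annotated genes at bases 36816205 to 36816278 of chromosome 12, and Mir2137 in an intron of Zfp185 at bases 72992079 to 72992144 of chromosome X. The hairpin of miR-6236 shares a 20-base word with transcripts of 6 other genes. No locus was found for miR-3535, and the number was 0 for the others that fell. Of 327 miRNAs 7 passed, 0 up and 7 down, with 32 at an unadjusted p under 0.05 by limma, and 48 separated the groups, against 10% by chance. Equal summed antilogs shifted the median by 0.13 and gave 4 calls, centring shifted it by 0.13, and a minimum of log2 5 gave 3 calls.

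The number of liver calls hung on single libraries. It was 4 without the TRIzol library A7_B2, 14 (5 up) without the TRIzol library B1 and 4 without the TraPR library A8_B2. The call of miR-3535 ended without any 1 of TRIzol A7_B2, TRIzol A8_B2, TraPR A8_B2 and TraPR B1 (adjusted p up to 0.233 by limma), that of miR-6236 without any 1 of TRIzol A7_B2, TRIzol A8_B2, TraPR A7_B2 and TraPR A8_B2 (up to 0.143) and that of miR-5121 without TRIzol A7_B2, TraPR A7_B2 or TraPR A8_B2 (up to 0.104). None of these 3 passed with columns scaled to the same summed antilog.

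By list, the entries with high numbers carried the liver difference. They had 0 up and 7 down of 28 (0 and 8 adjusted over the list alone), a median of -0.19 (-0.06 and -0.05 under the other scalings) and a mean of -0.96 (camera, adjusted p = 1.46e-05, and 0.0390 with an estimated correlation, the highest of 9 alternatives from 2.77e-06). No member of the hepatocyte (14 tested, median 0.05), erythroid (5, -0.07), leukocyte and platelet (8, 0.09), stromal and smooth muscle (10, -0.64), let-7 (21, 0.27), miR-17-92 (14, 0.25) or Dlk1-Dio3 (11, -0.34) lists passed, nor any of 76 less abundant arms (-0.06), and their camera tests gave adjusted p from 0.0580 to 0.852. Adjusted over the list alone, 2 let-7 members rose and 0 members of the other 7 lists passed. The scaling alternatives turned the erythroid median to 0.06, that of the less abundant arms to 0.07 and no other. The less abundant arm was lower in 43 of 75 hairpins (exact two-sided sign test, p = 0.248, and p = 0.0474 without the TraPR library B1).

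**Figure D2:**
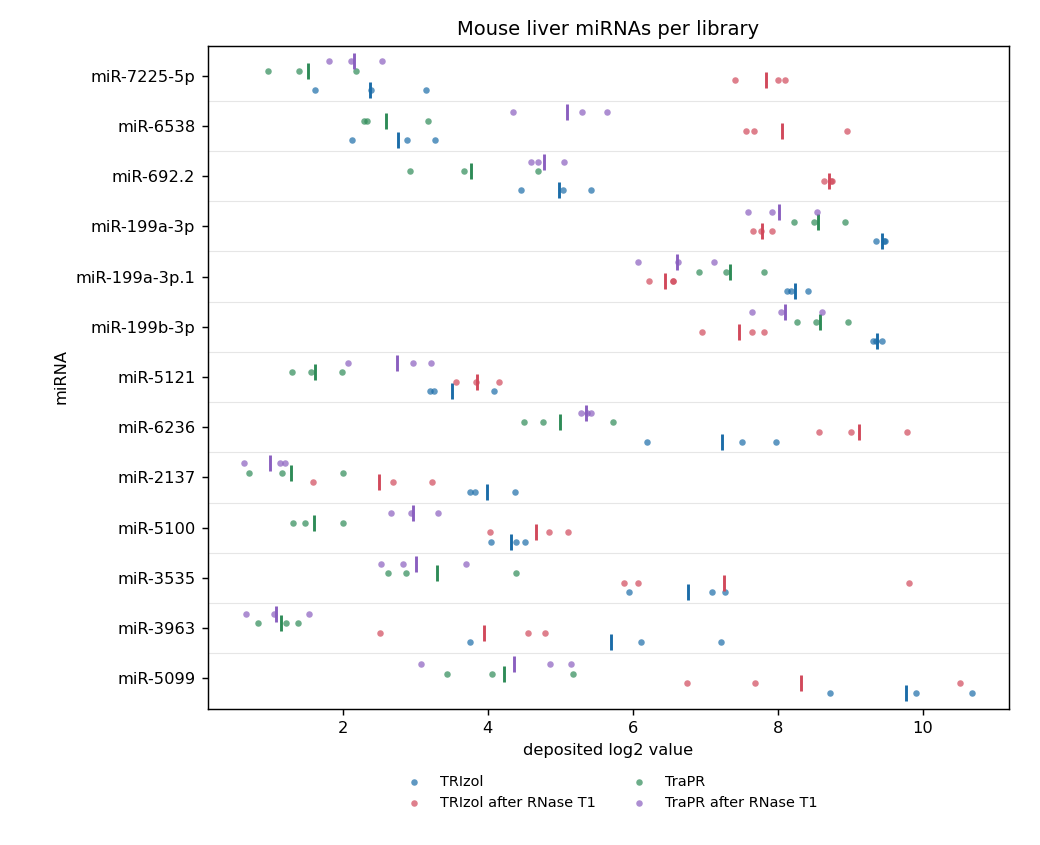
Log2 abundance in each liver library (dots) and group mean (ticks) for the miRNAs with the largest changes, in TRIzol and TraPR libraries with and without RNase T1. miR-7225-5p lay at 7.83 ± 0.38 in digested TRIzol libraries and at 2.16 ± 0.36 in digested TraPR libraries, and miR-5099 at 9.77 ± 0.99 in undigested TRIzol libraries and at 4.22 ± 0.88 in undigested TraPR libraries.

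RNase T1 raised a set of entries in TRIzol liver libraries. miR-7225-5p rose by 5.45 ± 0.43 (adjusted p = 9.42e-07, n = 3 per group), from 2.38 ± 0.76 to 7.83 ± 0.38, miR-6538 by 5.29 ± 0.48 and miR-692.2 by 3.73 ± 0.43. In GRCm38 Mir7225 overlaps an exon of Pde4dip at bases 97690509 to 97690562 of chromosome 3, and Mir6538 an intron of Rnf144a at bases 26414901 to 26415010 of chromosome 12. Fibroblast-rich miR-199b-3p changed by -1.90 ± 0.34 (adjusted p = 0.00197 by limma), its copies miR-199a-3p.1 by -1.80 ± 0.35 and miR-199a-3p by -1.66 ± 0.32, and none of these falls passed with columns scaled to the same summed antilog. Of 327 miRNAs 21 passed, 16 up and 5 down, and 66 separated the groups, against 10% by chance. The count was 38 (24 up and 14 down) without the TRIzol library B1 and 32 (19 up and 13 down) with the column-name suffix as a block. Without the filter on low values it was 79 of 970 tested (72 up and 7 down). Scaling to the same summed antilog shifted the median by 0.47 and left 16 up and 0 down.

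Entries with high numbers rose as a list after RNase T1 in TRIzol (8 up and 0 down of 28, 8 and 1 adjusted over the list alone, median 0.34, and 0.81 and 0.27 under the other scalings), with an adjusted p of 0.000363 by camera. The adjusted p was 0.0904 with an estimated correlation, the highest of 9 alternatives from 6.07e-06. The stromal and smooth muscle list had 0 up and 3 down of 10 (0 and 4 adjusted over the list alone), with a median of -0.60 and an adjusted p of 0.0176 by camera. Under summed antilog scaling its median was -0.13 and none of its members passed. With an estimated correlation the adjusted p was 0.289 (alternatives 0.00557 to 0.289), 0.157 without the TRIzol library B1 and 0.0635 without the digested TRIzol library A8_B2.

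In TraPR liver libraries 1 miRNA passed after RNase T1. miR-6538 rose by 2.49 ± 0.48 (adjusted p = 0.0381 by limma, n = 3 per group), the only 1 of 327 miRNAs that passed, with 23 at an unadjusted p under 0.05 and 67 separating the groups, against 10% by chance. The call ended without any 1 of the undigested libraries A8_B2 and B1 and the digested libraries A7_B2 and A8_B2 (adjusted p up to 0.255 by limma, and 0.00255 to 0.265 over its 13 alternatives). With the column-name suffix as a block limma called 2. The median of all miRNAs shifted by 0.11 with columns scaled to the same summed antilog and by -0.14 with centring, and both then gave 0 calls, as did the fit without the filter on low values and that of only the 2 groups. The entries with high numbers had 1 up and 0 down of 28 (3 and 0 adjusted over the list alone), with a median of 0.19 (0.30 and 0.05 under the other scalings) and an adjusted p of 0.0108 by camera. The adjusted p was 0.271 with an estimated correlation (alternatives 0.00269 to 0.271), 0.0668 without the undigested library A8_B2 and 0.0832 without the digested library A7_B2.

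After RNase T1 several entries were lower in TraPR than in TRIzol liver libraries. miR-7225-5p, which digestion had raised in TRIzol, was lower in TraPR (-5.68 ± 0.43, adjusted p = 5.49e-07 by limma, n = 3 per group), as were miR-3535 (-4.24 ± 0.83) and miR-5099 (-3.95 ± 0.84), which were lower without digestion too. The myeloid miR-223-3p (1.29 ± 0.36) and the copies let-7c-5p.1 (1.23 ± 0.34) and let-7c-5p (1.21 ± 0.33) rose, each at an adjusted p of 0.0407 by limma, and each call ended without any 1 of the 6 libraries except the TraPR library B1 (adjusted p up to 0.219, and from 0.00553 to 0.537 over their alternatives). Of 327 miRNAs 22 passed, 3 up and 19 down, and 71 separated the groups, against 10% by chance. Without the filter on low values 141 of 970 passed, 4 up and 137 down. Summed antilog scaling shifted the median by -0.23 and gave 0 up and 18 down. The entries with high numbers had 0 up and 12 down of 28 (0 and 14 adjusted over the list alone), a median of -1.25 and an adjusted p of 2.57e-10 by camera, and 0.00487 with an estimated correlation, the highest of 9 alternatives from 2.63e-11.

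Tested directly, the effect of RNase T1 differed between the isolations for 8 of 327 miRNAs, all with the lower effect in TraPR. The interaction was -4.81 ± 0.61 for miR-7225-5p (adjusted p = 0.000284 by limma), -3.87 ± 0.51 for miR-8094 and -3.34 ± 0.68 for miR-682 (n = 3 per group). The count was 4 without the undigested TRIzol library A8_B2, 3 without the digested TRIzol library A7_B2, 3 without the digested TRIzol library A8_B2, 2 without the undigested TraPR library A7_B2, 2 without the undigested TraPR library A8_B2, 4 without the digested TraPR library A8_B2 and 2 without the digested TraPR library B1. The call of miR-682 ended in 5 of the 12 fits with a library left out (the digested TRIzol libraries A7_B2 and A8_B2, the undigested TraPR libraries A7_B2 and A8_B2 and the digested TraPR library B1, adjusted p up to 0.0683 by limma). Equal summed antilogs shifted the median by -0.36 and gave 5 calls, and without the filter on low values 13 passed.

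As lists, the Dlk1-Dio3 cluster had a positive interaction in liver (0 up and 0 down of 11, also adjusted over the list alone, median 0.69, and 0.33 under summed antilog scaling) and the entries with high numbers a negative one (0 up and 4 down of 28, 0 and 5 adjusted over the list alone, median -0.27, and -0.63 under summed antilog scaling), each at an adjusted p of 0.0190 by camera. With an estimated correlation the adjusted p was 0.33 for both (alternatives 0.00779 to 0.33 and 0.00165 to 0.379). Without the undigested TRIzol library A8_B2, the undigested TraPR library A8_B2 or the digested TraPR library B1 the first gave 0.138, 0.0537 and 0.0808, and without the undigested TRIzol library B1 or the digested TraPR library B1 the second gave 0.379 and 0.0759.

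In plasma with the Lexogen kit, TraPR had less of miR-19 and of several entries with high numbers than TRIzol. miR-6538 (-7.24 ± 0.67, adjusted p = 1.56e-07), miR-5099 (-7.24 ± 0.68), miR-6240 (-6.15 ± 0.59), miR-5126 (-6.06 ± 0.74) and miR-6236 (-5.55 ± 0.64) changed most (n = 4 per group). Of the oncogenic miR-17-92 cluster and its paralogs, miR-19a-3p changed by -3.88 ± 0.41, miR-19b-3p by -3.41 ± 0.33 and miR-19b-3p.1 by -3.16 ± 0.47. All 4 TraPR libraries lay below all 4 TRIzol libraries for these 8, which the rule for naming them required. The hairpins of miR-6236, miR-6240 and miR-5126 share a 20-base word with transcripts of 6, 3 and 1 other genes. For miR-19b-3p and its copy the number was 1, and for miR-6538, miR-5099 and miR-19a-3p it was 0. Whether fragments of other RNAs contribute to these falls was not tested. Mir19a lies in an exon of the host gene Mir17hg at bases 115044000 to 115044081 of chromosome 14 in GRCm38. miR-181a-2-3p rose by 1.57 ± 0.40 (adjusted p = 0.0129 by limma) and miR-125a-5p by 1.11 ± 0.29 (adjusted p = 0.0135, and 0.0632 without TraPR replicate 3). miR-142a-5p of leukocytes rose by 0.94 ± 0.30 (adjusted p = 0.0426 by limma), a call that ended without any 1 of the 8 libraries except TRIzol replicate 4 (adjusted p up to 0.128), and the lymphocyte miR-150-5p by 1.01 ± 0.32 (adjusted p = 0.0426) with overlapping libraries. None of these 4 rises passed under summed antilog scaling.

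With the Lexogen kit, 31 of 277 plasma miRNAs passed, 4 up and 27 down, and 60 separated the groups, against 2.86% by chance. Libraries with the same replicate number deviated together, and with the number as a block within the kit 58 passed, 26 up and 32 down. Scaling to the same summed antilog shifted the median by -0.19 and gave 0 up and 18 down, and centring shifted it by 0.30 and gave 26 up and 23 down.

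Of the plasma lists with the Lexogen kit, miR-17-92 and its paralogs passed, with 0 up and 9 down of 17 (2 and 10 adjusted over the list alone), a median of -1.34 (-1.53 and -1.04 under the other scalings) and an adjusted p of 0.00107 by camera. The adjusted p was 0.485 with an estimated correlation, the only 1 of 12 alternatives (0.000457 to 0.485) that missed the threshold. The others did not pass (adjusted p 0.0780 to 0.984 by camera): leukocyte and platelet miRNAs had 2 up and 0 down of 10 (median 0.41), let-7 0 up and 3 down of 16 (-0.33), entries with high numbers 0 up and 5 down of 21 (-0.08) and less abundant arms 0 up and 3 down of 49. No member passed in the hepatocyte (8 tested), erythroid (7), stromal and smooth muscle (9), striated muscle (5), Dlk1-Dio3 (14) or Sfmbt2 (3) lists, also adjusted over the list alone. Adjusted over the list alone the counts were 2 and 0, 3 and 4, 0 and 5, and 0 and 1 in the 4 lists with calls. The stromal list's median of 0.01 and mean of -0.12 differed in sign, as did those of the less abundant arms (0.00 and -0.05). Summed antilog scaling turned these medians to -0.18 and -0.19, and centring turned that of the entries with high numbers to 0.22.

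**Figure D3:**
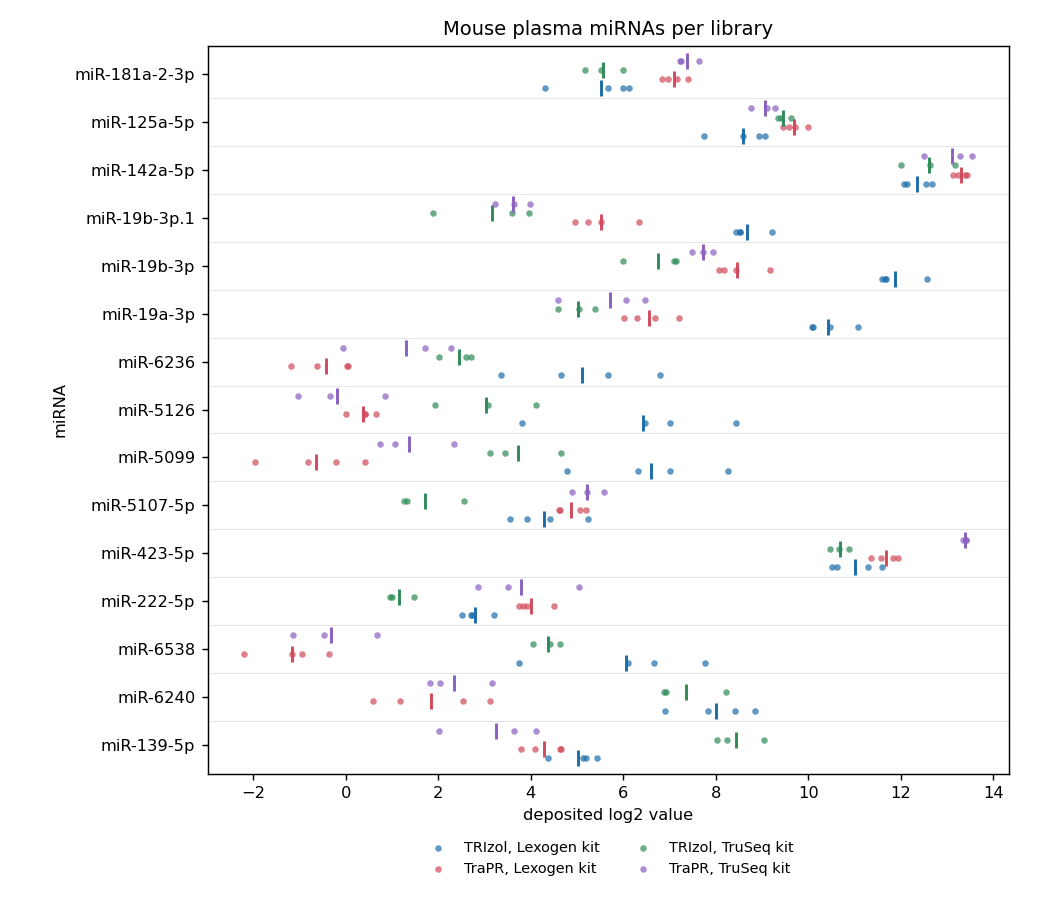
Log2 abundance in each plasma library (dots) and group mean (ticks) for the miRNAs with the largest changes between TraPR and TRIzol with either kit. With the Lexogen kit miR-19a-3p lay at 6.55 ± 0.51 in TraPR and 10.4 ± 0.46 in TRIzol, and with the TruSeq kit at 5.71 ± 0.98 and 5.01 ± 0.40.

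With the TruSeq kit, miR-139-5p of plasma fell most in TraPR, and miR-6240 and miR-6538 were lower as with the Lexogen kit. miR-139-5p changed by -5.18 ± 0.56 (adjusted p = 3.58e-06, n = 3 per group), from 8.44 ± 0.53 to 3.25 ± 1.1, miR-6240 by -5.0 ± 0.68 and miR-6538 by -4.69 ± 0.78. miR-5107-5p rose by 3.51 ± 0.56, miR-423-5p by 2.71 ± 0.31 and miR-222-5p by 2.65 ± 0.56. The erythroid miR-451a changed by -2.72 ± 0.47 (adjusted p = 0.000354 by limma). Mir139 lies at bases 101475376 to 101475443 of chromosome 7 and Mir423 in an intron of Nsrp1 at bases 77078064 to 77078172 of chromosome 11 in GRCm38.

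In all 39 of 277 plasma miRNAs passed with the TruSeq kit, 7 up and 32 down, and 75 separated the groups, against 10% by chance. The count was 20 (7 up and 13 down) without TRIzol replicate 3, 23 (6 up and 17 down) with only these 2 groups fitted and 65 (17 up and 48 down) with the replicate number as a block within the kit. Equal summed antilogs gave 4 up and 13 down, and centring shifted the median by 0.35 and gave 13 up and 17 down. None of the 11 lists passed camera (adjusted p 0.759 to 0.910). Down in both kits were 8 miRNAs against 3.12 for independent lists (exact one-sided hypergeometric test, p = 0.00606): miR-5126, miR-6538, miR-5099, miR-6240, miR-296-5p, miR-221-3p, let-7a-1-3p and let-7c-2-3p. Calls with the kits share the variance estimate of the same fit, so they are not independent. Near-identical copies, such as let-7a-1-3p and let-7c-2-3p, also counted as separate names in that test. Over all 277 miRNAs the changes with the kits correlated weakly (Spearman 0.163, Pearson 0.342). Of 230 miRNAs tested in liver too, miR-5099 and miR-6236 fell both in liver and in Lexogen plasma (2 shared against 0.326, exact hypergeometric p = 0.0319), and miR-3535 and miR-5099 both in liver and in TruSeq plasma (2 against 0.404, p = 0.0485). As the liver calls of miR-6236 and miR-3535 each ended without any 1 of 4 libraries and under summed antilog scaling, only miR-5099 is then shared in either comparison.

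Whether the difference between isolations differed between the libraries of the kits was tested directly in plasma. A kit effect cannot be told apart here from other differences between these sets of libraries. The interaction was 4.88 ± 1.03 for miR-5099 (adjusted p = 0.00417 by limma), 4.58 ± 0.62 for miR-19a-3p (6.91e-05) and 4.42 ± 0.98 for miR-6236, whose log2 changes were lower with the Lexogen kit, and the calls of miR-5099 and miR-6236 ended without the filter on low values. With the TruSeq kit miR-19a-3p did not fall, but its mean in TruSeq TRIzol libraries was already below that of either Lexogen group. Whether this lower start hid a fall was not tested, and values in plasma reached down to -2.96. The interaction was -4.45 ± 0.74 for miR-139-5p (adjusted p = 0.000511 by limma), -4.08 ± 0.74 for miR-185-5p and -3.58 ± 1.02 for miR-23b-3p, and the last call ended in 8 of the 14 fits with a library left out (Lexogen TRIzol replicate 4, Lexogen TraPR replicates 2, 3 and 4, TruSeq TRIzol replicates 1, 2 and 3 and TruSeq TraPR replicate 3, adjusted p up to 0.0742, and 0.00575 to 0.281 over its 21 alternatives). Of 277 miRNAs 25 passed, 13 up and 12 down. The count was 14, 16 and 15 without Lexogen TraPR replicates 2, 3 and 4, 13 and 15 without TruSeq TRIzol replicates 2 and 3, and 51 (25 up and 26 down) with the replicate number as a block within the kit. Without the filter on low values 10 passed. Scaling to the same summed antilog shifted the median by 0.27 and gave 6 up and 2 down. The miR-17-92 list had a positive interaction (4 up and 0 down of 17, 5 and 0 adjusted over the list alone, median 1.09), at an adjusted p of 0.00228 by camera. With an estimated correlation the adjusted p was 0.60 (alternatives 0.000241 to 0.60) and 0.0618 without TruSeq TraPR replicate 1.

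Plasma profiles differed more between the kits than between the isolations. Deviations of the same replicate number did not correlate between kits (mean -0.005 within TRIzol and -0.061 within TraPR). The labels do not say whether both kits were run on the same plasma. The kit thus cannot be told apart from a difference between samples or batches. Within TRIzol, miR-669c-5p of the Sfmbt2 cluster changed by -6.80 ± 0.60 from Lexogen to TruSeq (adjusted p = 2.59e-08), the muscle miRNA miR-206-3p by -6.14 ± 0.62 and miR-19b-3p.1 by -5.52 ± 0.51, while endothelial miR-126a-5p rose by 5.65 ± 0.61, miR-411-5p by 3.91 ± 0.81 and miR-183-5p by 3.45 ± 0.71. The red cell miRNAs miR-486a-5p (3.13 ± 0.52) and miR-486b-5p (2.95 ± 0.56) rose, with 0.96 and 0.78 left under summed antilog scaling. Within TraPR, miR-669c-5p changed by -6.30 ± 0.60, miR-1a-3p.1 by -6.06 ± 0.58 and miR-7a-5p.1 by -6.05 ± 0.53, and miR-411-5p rose by 3.39 ± 0.81, miR-410-3p by 3.32 ± 0.57 and miR-381-3p by 3.11 ± 0.73. Under summed antilog scaling miR-183-5p within TRIzol and miR-411-5p and miR-381-3p within TraPR did not pass. The most abundant miRNA took 24.2% ± 2.41 and 25.5% ± 3.88 of the summed antilogs with the Lexogen kit (TRIzol and TraPR, n = 4 each) and 41.9% ± 8.06 and 44.0% ± 3.41 with the TruSeq kit (n = 3 each), each at the smallest exact two-sided permutation p of 0.0571 (adjusted 0.4). In every plasma library it was miR-486a-5p or miR-486b-5p. These copies were not summed, so the shares understate miR-486 as a whole.

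The kit calls numbered 129 of 277 miRNAs within TRIzol (49 up, 80 down, 135 separating the groups) and 108 within TraPR (38 up, 70 down, 127 separating the groups), against 5.71% separated by chance. The same 21 rose and the same 48 fell in both, against 6.72 and 20.2 for independent lists. These calls too share the variance estimate of the same fit, count near-identical copies as separate names and are not independent. Summed antilog scaling shifted the medians by -2.17 and -1.90 and gave 5 up and 213 down within TRIzol and 4 up and 200 down within TraPR, and centring shifted them by 0.47 and 0.52 and gave 67 up and 56 down and 62 up and 46 down.

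Lists passed camera in the kit comparisons, and none held with an estimated correlation. Erythroid miRNAs were up within TRIzol (4 up and 0 down of 7, also adjusted over the list alone, median 1.55, adjusted p = 0.0466) and within TraPR (4 and 0 of 7, also adjusted over the list alone, median 1.38, adjusted p = 0.0461), with medians of -0.62 and -0.52 under summed antilog scaling. The adjusted p was 0.571 and 0.487 with an estimated correlation (alternatives 0.00704 to 0.571 and 0.00506 to 0.487). The let-7 family was down within TRIzol (0 up and 10 down of 16, also adjusted over the list alone, median -1.37, and -3.54 and -0.90 under the other scalings, adjusted p = 0.0122 by camera). With an estimated correlation the adjusted p was 0.571 (alternatives 0.000260 to 0.571). Leukocyte and platelet miRNAs were down within TraPR (0 up and 6 down of 10, also adjusted over the list alone, median -1.60, and -3.51 and -1.08 under the other scalings, adjusted p = 0.0461). The adjusted p was 0.487 with an estimated correlation (alternatives 0.0330 to 0.487). Left-out libraries ended the erythroid calls within TRIzol (0.0879 without Lexogen replicate 1, 0.0531 without Lexogen replicate 3, 0.111 without TruSeq replicate 1) and within TraPR (0.122 without Lexogen replicate 1, 0.0510 without Lexogen replicate 2, 0.122 without TruSeq replicate 1, 0.0543 without TruSeq replicate 3). They also ended the leukocyte call (0.0515 without Lexogen replicate 1, 0.0510 without Lexogen replicate 2, 0.104 without TruSeq replicate 1, 0.0543 without TruSeq replicate 3).

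**Figure D4:**
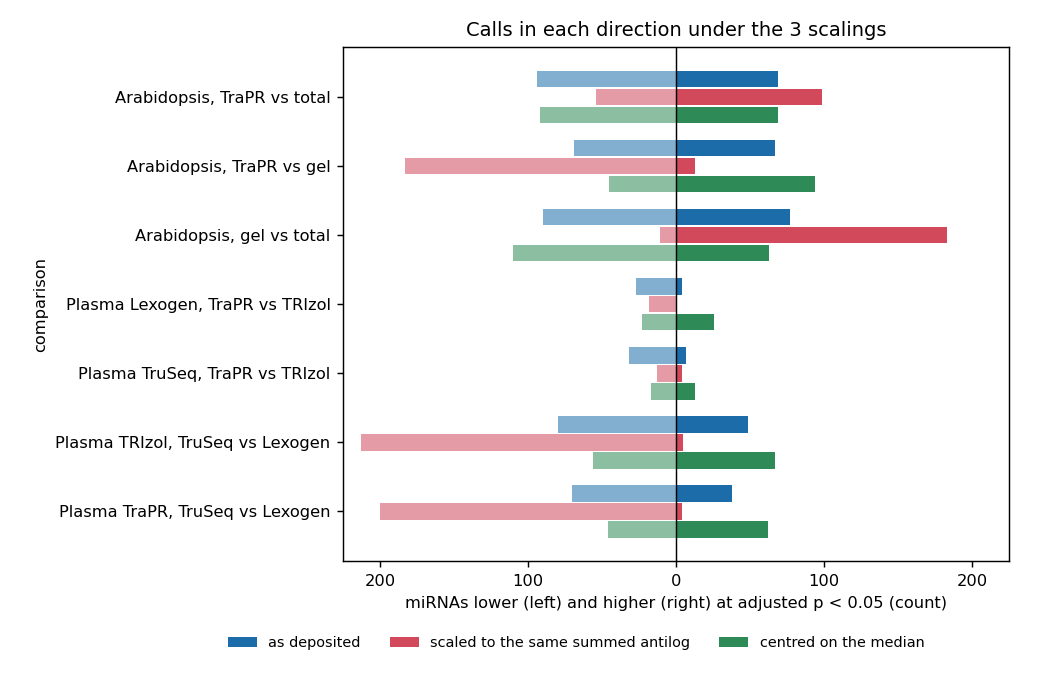
Number of miRNAs called higher and lower (bars from 0) in 7 comparisons under the deposited scaling, columns scaled to the same summed antilog and columns centred on their median. Between gel-selected and total Arabidopsis RNA the calls were 77 up and 90 down as deposited, 183 and 11 with the same summed antilog and 63 and 110 with centring.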

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

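The checks of explanations in the next 3 paragraphs were chosen after the results were seen, and no biological explanation was tested. The camera test of the fixed list and the fit without the filter on low values, also quoted there, were planned. Summed antilog scaling stood in for planned size factors.

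16 entries were higher after RNase T1 in TRIzol liver libraries, with a median of 2.70. A difference in scaling is argued against by a lowest median of 2.64 under the other scalings. A low level stays open: the 203 other tested miRNAs with mean values from 2.30 to 8.05 had a median of -0.0239, but without the filter on low values 72 rose and 7 fell. That was among 970 tested, against 16 and 5 among 327 with the filter. Of the 15 names with a locus, 8 (53.3%) shared a 20-base word with another gene's transcripts, against 31 of 274 others (11.3%, two-sided Fisher's exact test, p = 0.000175). Fragments of other RNAs that match these hairpins could contribute to these 8. The 2 entries that rose most, miR-7225-5p and miR-6538, shared no such word, but genes that overlap a hairpin were left out of the search. Pde4dip, whose exon Mir7225 overlaps, could therefore not count, and nor could Rnf144a for Mir6538. The search cannot decide for these 2 entries, and for them the cause stays open.

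The miR-17-92 list was lower in TraPR than in TRIzol plasma with the Lexogen kit, with a median of -1.34, at an adjusted p of 0.00107 by camera but of 0.485 with an estimated correlation, so the list as a whole stays uncertain. Scaling is argued against by a median of -1.04 where it was highest, and a single library by a median of -1.04 without TRIzol replicate 4. The sum over miR-19a and miR-19b differed by -3.49 and that over miR-17, miR-20, miR-93 and miR-106 by -1.53, but falls of the members already seen fixed these signs, so the sums are no separate test. All 3 miR-19 names fell, which exchange of reads between them alone does not produce. Whether reads moved within either set, and why the list was lower with this kit, stays open.

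miR165 and miR166 were lower in gel-selected than in total Arabidopsis RNA, with a median of -5.39 over 9 names. The median was -2.38 where scaling moved it most, which argues against scaling alone. All 9 names fell, which exchange of reads between them alone does not produce, though some may have been exchanged, and the share of the family, which had to fall with them, differed by -57.4 percentage points. The lowest change among the other abundant miRNAs was -3.17, outside the family's range of -5.53 to -5.09. Whether the gel step or another difference between these libraries lowered the family stays open.

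Chance was examined with other splits of the libraries, chosen after the results were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the true split gave the only call count of its size (1 of 10) with at most 0 calls in any other: 163, 136 and 167 in Arabidopsis, 7, 21, 1 and 22 in liver and 39 in TruSeq plasma. In Lexogen plasma 1 of 35 splits, the true one with 31 calls, reached its count, and the highest other count was 0, also among the 8 splits that part every pair of replicate numbers. If equal numbers mark pairs, only those 8 can be exchanged, and they too are too few for a share under 0.05. For the kits within TRIzol and TraPR the true splits gave 129 and 108, the highest others 74 and 50, and 1 of 35 splits reached the true count in both. The plasma interaction gave 25 against at most 20 in other splits (1 of 100), and the liver interaction 8, a count reached by 10 of 100 splits with up to 22. Splits for an interaction exchange isolation labels within a condition, which carries the difference between isolations into it (the liver split with 22 exchanged all undigested libraries), so these counts do not tell whether chance can be excluded.

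TRIzol replicate 4 of the Lexogen plasma libraries lay far above the other 3 by Dixon's ratio, past its critical value for 4 libraries. The ratio was 0.910 for miR-19b-3p (12.56 against 11.60 to 11.68), 0.901 for its copy miR-19b-3p.1 (9.22 against 8.44 to 8.52) and 0.848 for the median of tested miRNAs (6.78 against 6.13 to 6.23). In 80 groups of 4 tested, 3 were outlying and 4 would be by chance.

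Some effects differed between conditions by a direct interaction test in limma. In liver the effect of RNase T1 was lower in TraPR for miR-7225-5p (-4.81), miR-8094 (-3.87) and miR-682 (-3.34, lost in 5 of 12 fits with a library left out), and the Dlk1-Dio3 and high-number lists differed at adjusted p = 0.0190 each by camera. Neither list held with an estimated correlation (adjusted p = 0.33 each), and left-out libraries ended both calls (up to 0.138 and 0.379). In plasma the effect of TraPR differed between the libraries of the kits for miR-5099 (4.88), miR-19a-3p (4.58), miR-6236 (4.42), miR-139-5p (-4.45), miR-185-5p (-4.08) and miR-23b-3p (-3.58), and for the miR-17-92 list at adjusted p = 0.00228 by camera. Of these, miR-5099 and miR-6236 did not pass without the filter on low values (adjusted p = 0.0589 and 0.0699), and miR-23b-3p did not pass there (0.281) and in 8 of 14 fits with a library left out (up to 0.0742). The list did not hold with an estimated correlation (adjusted p = 0.60) or without TruSeq TraPR replicate 1 (0.0618).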

How the results depend on the processing

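Counts of calls moved more than 1.5 times, or lost or gained all calls, in these alternatives. Filters also change the number tested: without one, 243 fly IDs, 970 liver names and 1168 plasma names were tested. Centring, a minimum of log2 5, averaged copies, a variance without trend and the blocks by liver suffix and within plasma kits were chosen after seeing the data. A minimum of log2 5 gave 108 calls of 147 tested for Arabidopsis TraPR against total RNA, where the main fit gave 163 of 229. For liver TraPR against TRIzol it gave 3 of 246. For fly TraPR 50 against ribodepleted RNA, centring gave 26 and fitting only the 2 groups 26, and the trend without a filter on low values gave 1. In liver, scaling to the same summed antilog gave 4 for TraPR against TRIzol. RNase T1 in TRIzol gave 79 (72 up and 7 down) without the filter and 32 with the suffix block. RNase T1 in TraPR gave 0 with summed antilogs, 0 with centring, 0 without the filter, 0 with only the 2 groups and 2 with the suffix block. TraPR against TRIzol after RNase T1 gave 141 (4 up and 137 down) without the filter, and the liver interaction 5 with summed antilogs and 13 without the filter. In plasma, Lexogen gave 18 with summed antilogs, 49 with centring and 58 with the block within the kit. TruSeq gave 17 with summed antilogs, 23 with only the 2 groups and 65 with the block. The kits gave 218 within TRIzol and 204 within TraPR with summed antilogs. The plasma interaction gave 8 with summed antilogs, 10 without the filter and 51 with the block.

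With 1 library left out, counts ranged from 5 to 23 for fly TraPR 50, 4 to 14 for liver TraPR against TRIzol, 17 to 38 for RNase T1 in TRIzol, 0 to 1 for RNase T1 in TraPR, 2 to 10 for the liver interaction, 20 to 41 for TruSeq plasma and 13 to 32 for the plasma interaction. The liver arm shift ranged from -0.115 to -0.0281. The lowest replicate correlation went from 0.968 to 0.959 in Arabidopsis, 0.998 to 0.994 in fly, 0.987 to 0.950 in liver and 0.957 to 0.923 in plasma when only tested miRNAs were used.

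With replicate number as a block the counts were 159, 133 and 165 in Arabidopsis, 24, 107, 0 and 0 in fly, and 34 (Lexogen), 44 (TruSeq), 131 and 114 (kits) and 29 (interaction) in plasma. Same-number deviations correlated at -0.157 to 0.121 in Arabidopsis, 0.099 to 0.191 within the TruSeq kit and -0.109 to 0.195 between plasma kits, so these groups were not taken as paired, and fly groups have only 2 numbers. The liver columns carry no replicate numbers, and the column-name suffix, whose meaning the labels do not give, was the only block that could be fitted there.

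Of 248 named calls under 3371 settings, 2992 stayed, 344 weakened and 35 reversed, all of the last with summed antilogs. In Arabidopsis TraPR against total RNA these were miR780.2 (0.19), miR822-5p (0.21) and miR162a-3p (0.0767). Against gel-selected RNA they were miR159b-3p (-1.30), miR839-5p (-1.0), miR858a (-0.88), miR408-3p (-0.59), miR403-3p (-1.43), miR167a-5p (-0.97), miR173-3p (-1.12), miR780.2 (-0.29) and miR319a (-1.36). In gel-selected against total RNA they were miR159b-3p (2.24), miR390a-5p (1.94), miR408-3p (2.19), miR173-3p (0.17), miR166b-5p (1.12), miR780.2 (0.48), miR168a-5p (1.14), miR319a (1.91), miR824-3p (0.74), miR398b-3p (0.52), miR398c-3p (0.24) and miR390b-5p (1.90). Between kits within TRIzol they were miR-144-5p (-0.62), miR-10a-5p (-0.10), miR-541-5p (-0.31), miR-92a-3p (-0.31), miR-143-3p (-0.83) and miR-16-5p.1 (-0.95), and within TraPR miR-92a-3p (-0.0793), miR-378a-3p (-1.13), miR-143-3p (-0.50), miR-10b-5p (-0.37) and miR-25-3p (-0.18).

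Relative log expression factors, the DESeq2 test, a filter on 5 counts and thinning to equal depth were not run because the tables hold no counts, and the cause of these differences was not tested.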

Other observations

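In liver, deviations from the group means correlated between undigested and digested libraries that share a column-name suffix, at 0.483 to 0.533 in TRIzol and 0.238 to 0.724 in TraPR. Other suffixes in TraPR correlated as highly in places: digested A8_B2 with undigested A7_B2 at 0.640, against 0.238 for A8_B2 with itself, and digested A7_B2 with undigested A8_B2 at 0.293. Between digested TraPR and undigested TRIzol libraries of the same suffix the correlations were 0.188 to 0.417, and between undigested TraPR and undigested TRIzol libraries -0.208 to 0.091. The labels do not explain the suffixes.

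Between-group Pearson correlations over miRNAs were 0.679 to 0.721 for gel-selected and total Arabidopsis RNA, 0.831 to 0.863 for gel-selected RNA and TraPR, and 0.743 to 0.787 for total RNA and TraPR. In fly ovary they were 0.992 to 0.995 between TraPR and ribodepleted RNA and 0.916 to 0.926 between TraPR and oxidized RNA.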
